A study of Mus musculus with 6 samples.

How the data were processed

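Retina samples, 3 of Emcn+/+ and 3 of Emcn-/- genotype, from postnatal day 15 in the oxygen-induced retinopathy model were profiled. Per the labels' protocols, 1.3 µg of total RNA per library was selected for poly-A transcripts, fragmented and reverse transcribed with random primers. The protocol text covers both a strand-marking and an unmarked second strand, so whether the libraries keep strand is not known here, and reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes the genome build was GRCm38. The aligner, counter and annotation release are not given in the sources used here.

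The deposited table holds a read signal per gene, whose values are not whole numbers and are not adjusted for gene length. How the authors scaled it is not given in the sources used here, and it was worked out from the values. In each library 100% of the values were whole multiples of 1 step (tolerance 0.001 of a read), between 0.924 and 1.09 normalised reads, as read counts divided by 1 factor per library give, and read counts were recovered by dividing by that step. The inverse steps, 0.916 to 1.08, equal the median-ratio size factors that DESeq2 computes from the recovered reads. The order of genes in the table followed the p-values of a DESeq2 fit of Emcn-/- against Emcn+/+ (Spearman correlation 1.0), so DESeq2 is an alternative close to the table's own ordering. Recovered totals were 14865868 to 17087621 reads per library. At this depth 1 read was worth about 1 normalised read, and the limit that a count of 0 allows (3 reads) was 2.77 to 3.28 normalised reads; such limits and intervals cover counting error only. All 6 value columns were used.

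The table pairs gene IDs with symbols. Of its 28627 gene IDs, 27390 were found in GENCODE M21 (GRCm38), which gave positions and exonic lengths, and 1237 were not, some of them newer than that release. Of the tested genes, 98.4% had an exonic length. A symbol carried by several IDs (21 symbols) was assigned to the ID with the highest mean.

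Before the data were examined, an edgeR quasi-likelihood test on counts with TMM scaling was planned. Because the table holds normalised values, the main test was instead limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), with genotype as the only term and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Fold changes are on that scale and understate the change of low genes. Genes were kept by edgeR's expression filter on the recovered reads (minimum count 10), which left 16681. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2 removes weakly expressed genes from its adjustment: at a mean of 494 normalised reads the filter left 6417 genes with an adjusted p, and Emcn, with a mean of 47.0, had none. Without that filter DESeq2 called 49 genes, Emcn among them.

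Lists of genes for cell types, vascular processes, signalling pathways and neighbouring tissues were fixed in the same plan (35 lists, 616 of 632 symbols found). They were tested with camera from limma on the same log values with a preset correlation of 0.01 between genes, 2-sided, adjusted over the 35 lists, each with at least 4 tested members. The calls were 7 with the preset correlation and 0 with an estimated correlation. Each of the 10 splits of the 6 libraries into 3 and 3 called at least 7 lists with the preset correlation. Per-library list means were compared with exact permutation tests, for which 3 against 3 cannot give a p under 0.1. Emcn is in no list, and some genes are in several lists.

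Genes were named by a rule from the same plan, which left out predicted genes, pseudogenes and IDs without a standard name. It took Emcn first, then up to 10 genes in each direction past the threshold without overlap of the genotypes, then up to 4 list members past it, with the genes of smallest p filling up to 20. It added 16 genes named whatever their value, the 2 members with the smallest p of each called list, and the member with the highest mean of each list of a neighbouring tissue.

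The replicate numbers follow the order of the samples and pair nothing. Alternatives covered the scaling, the filter on low values, the pseudocount, each library left out in turn, sex as a covariate, a block for the 2 number series of the sample titles, 1 surrogate variable (sva 3.50.0), gene types, the gene list test and the model. Removing a loess trend on log10 exonic length per library, a rod covariate and pseudocount 5 were chosen after seeing the data. So were gene exclusions by list, limma with TMM scaling and the unfiltered DESeq2 fit. The edgeR fit with TMM scaling was the test planned before. The scripts were tested on simulated data drawn from the real means, dispersions and size factors of the 16681 genes of this comparison, in 3 runs with 200 changed genes each. limma recovered 48.8% of 1.5-fold, 74.6% of 2-fold and 93.4% of 4-fold changes, with 29 false calls in all runs; edgeR recovered 49.8%, 75.6% and 93.9% with 33 false calls, and DESeq2 58.2%, 76.6% and 93.9% with 83. Camera called the raised list of 20 genes in 3 of 3 runs and 0 of 102 unchanged lists. Real libraries differ in ways these draws do not hold, such as the length trend. Each gene was also drawn on its own, so the simulated lists held no correlation between genes. The camera result therefore does not cover correlated lists, such as the pigment epithelium list (mean correlation 0.431 within genotypes).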

Results

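Poly-A RNA was sequenced in 6 mouse retina samples collected at postnatal day 15 in the oxygen-induced retinopathy model, 3 of Emcn+/+ pups and 3 of Emcn-/- littermates. In this model, pups are kept in high oxygen, in which retinal capillaries regress, and are then returned to room air, where the poorly perfused retina becomes hypoxic and new vessels sprout. Emcn encodes endomucin, a sialomucin of the endothelial surface coat. The libraries held between 14865868 and 17087621 reads assigned to genes, and between 23895 and 25243 genes had at least 1 read in a library. The labels do not say whether each sample came from a separate animal, so the p-values measure the spread between these samples. No pair of libraries differed by as little as sampling noise: between 23.9% and 43.1% of genes differed at an unadjusted threshold of 0.05 in the pairwise counts.

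The comparison asked which retinal transcripts differed between Emcn-/- and Emcn+/+ pups during oxygen-induced retinopathy. Emcn itself (ENSMUSG00000054690, GRCm38 chromosome 3, 137341067 to 137432185, plus strand) fell from 91.5 ± 10.05 normalised reads in Emcn+/+ retinas to 2.54 ± 1.86 in Emcn-/- retinas (SD, n = 3 each). The values were 93.3, 80.6 and 100.5 in the Emcn+/+ libraries and 1.95, 1.04 and 4.62 in the Emcn-/- libraries, so the measured genotype followed the label in each of the 6 libraries. The log2 fold change was -4.83 ± 0.40 (SE, on the log2(value + 1) scale), with a limma adjusted p of 0.0143. Summed over libraries, 8 reads in Emcn-/- against 269 in Emcn+/+ left 2.86% of the transcript level (95% exact interval 1.22% to 5.72%, counting error only). The value was lower in 3 of 3 Emcn-/- libraries, and an edgeR fit of the recovered reads gave -5.08 with an adjusted p of 0.00508. The limma call was lost when Emcn+/+ replicate 1 (-4.82, adjusted p = 0.0919), Emcn+/+ replicate 2 (-4.92, 0.209) or Emcn-/- replicate 1 (-4.77, 0.160) was left out. Over the limma alternatives the adjusted p ranged from 0.00225 to 0.399.

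**Figure D1:**
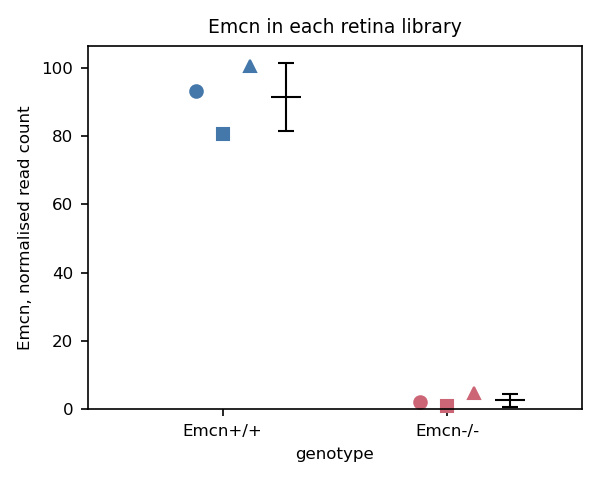
Normalised Emcn read count (vertical axis, linear, from 0) in each retina library by genotype; each symbol is 1 library and the black bar with whiskers is the mean ± SD of 3 libraries. The Emcn+/+ libraries lie between 80.6 and 100.5 and the Emcn-/- libraries between 1.04 and 4.62.

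Emcn was the only gene past an adjusted p of 0.05 among 16681 tested with limma, with 1 gene lower and 0 higher. edgeR on the recovered reads also called 1 gene, and 1358 genes had an unadjusted p under 0.05 with limma, 612 higher and 746 lower, where 834 would be expected by chance. The values of the 2 genotypes did not overlap for 2406 genes (14.4%, against 10% by chance). Of the 19 genes with the next smallest p that the naming rule allowed, 16 had lower values in Emcn-/- and 3 had higher values. The lower ones included Smg1, a kinase of nonsense-mediated decay (log2 fold change -0.44 ± 0.06 SE, limma adjusted p = 0.305), the histone methyltransferases Kmt2a (-0.44 ± 0.07, 0.305) and Kmt2d (-0.51 ± 0.09, 0.340), the histone acetyltransferase Crebbp (-0.34 ± 0.06, 0.305), the ubiquitin ligases Ubr4 (-0.44 ± 0.07) and Birc6 (-0.37 ± 0.06), and the nuclear envelope protein Syne1 (-0.48 ± 0.09). Tnrc6b, Usp9x, Ubn2, Dync1h1, Trrap, Ino80d, Tmem131, Akap9 and Nsd1 had log2 values between -0.24 and -0.38 and did not pass either. The 3 with higher values were Acta2, Ddit4l and Gapdh, and Gapdh is uncertain because its many processed pseudogenes can share its reads. Ddit4l lies close to Emcn on GRCm38 chromosome 3 (137621612 to 137628333), and whether its values follow from that position was not tested. DESeq2 on the same reads called 72 genes, 59 lower and 13 higher, with Smg1, Kmt2a, Kmt2d, Tnrc6b and Ubr4 among the lower ones and Apoe, Apln and Col9a1 among the higher ones. The genes DESeq2 called lower were long, with a median exonic length of 17713 bp against 4151 bp for all tested genes and 3149 bp for those called higher. Across 5 equal groups of exonic length, the median log2 fold change went from 0.08 in the shortest to -0.07 in the longest. The limma count depended on 1 library, because without Emcn+/+ replicate 3 it was 110 genes lower and 37 higher.

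**Figure D2:**
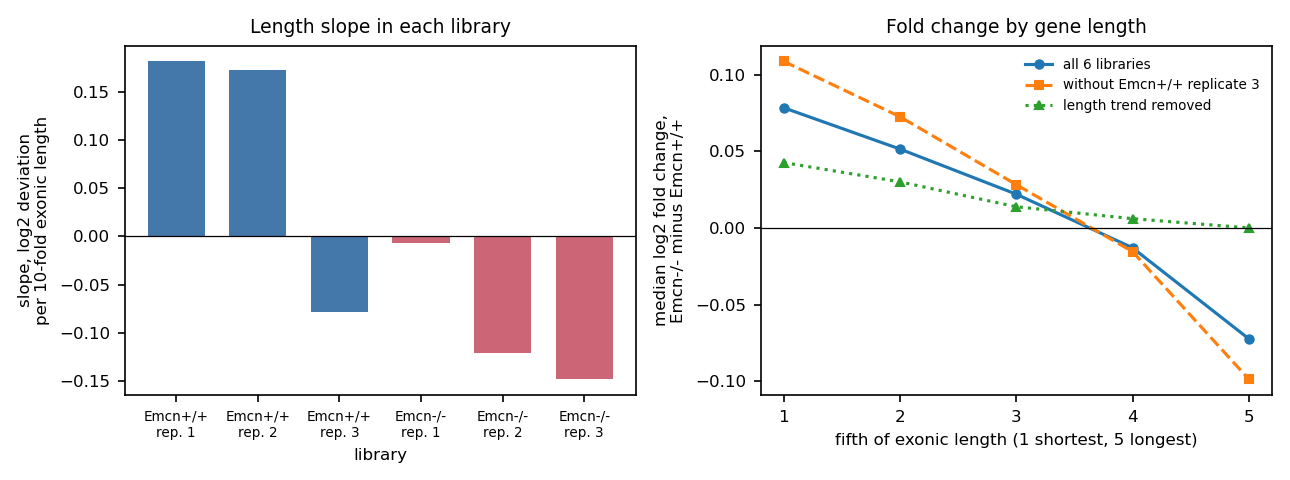
Left, slope of each gene's log2 deviation from its mean on log10 exonic length in each library (blue Emcn+/+, red Emcn-/-). Right, median log2 fold change (Emcn-/- minus Emcn+/+) in each of 5 equal groups of exonic length, for all libraries, without Emcn+/+ replicate 3 and with the length trend removed; the slope is 0.18 and 0.17 in Emcn+/+ replicates 1 and 2 and below 0 in the other libraries.

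Esm1, Apln and Angpt2, 3 genes of sprouting vessels, had higher values in Emcn-/- retinas without passing the test over all genes, while the tip cell list to which they belong did not pass. Esm1, a marker of endothelial tip cells (GRCm38 chromosome 13, 113209659 to 113218098), stood at 52.9 ± 26.3 normalised reads in Emcn+/+ and 102 ± 15.9 in Emcn-/- (SD, n = 3; log2 fold change 1.03 ± 0.31 SE, limma adjusted p = 0.482). Apln, a ligand secreted by tip cells, stood at 648 ± 133 and 1048 ± 143 (0.70 ± 0.15, adjusted p = 0.374 with limma and 0.000738 with DESeq2). Angpt2, which destabilises vessels during sprouting, stood at 190.3 ± 67.8 and 274 ± 3.75 (0.58 ± 0.21, limma adjusted p = 0.534). All 3 of these genes were higher in each Emcn-/- library than in any Emcn+/+ library. Of the 23 tested members of the tip cell list, 14 had positive and 9 negative log2 fold changes, 0 passed over all genes, and 1, Apln, was higher when adjusted over the list alone. The list had a median of 0.07 (camera adjusted p = 0.164), and Dll4, a Notch ligand of tip cells, was at -0.04. Emcn+/+ replicate 3 stood close to the Emcn-/- libraries for several of these genes: its Esm1 value was 83.0 against 41.5 and 34.3 in the other Emcn+/+ libraries, and its Angpt2 value was 268 against 141 and 162. Without that library the list passed (median 0.30, camera adjusted p = 0.000253), and it also passed without Emcn-/- replicate 2 (0.20, 0.00544), but its median turned negative without Emcn+/+ replicate 1 (-0.01, 0.491) or Emcn-/- replicate 3 (-0.05, 0.808). Without Emcn+/+ replicate 3 the genes passed too: Esm1, Apln, Angpt2 and the vasodilator peptide gene Adm had limma adjusted p of 0.0253, 0.0184, 0.0176 and 0.0296. That fit holds Emcn-/- replicate 3 as the only library of its title-number series, so series and genotype are not balanced in it. With all libraries Adm did not pass (0.50 ± 0.41, limma adjusted p = 0.759), and its value of 181 in Emcn+/+ replicate 3 lay above the Emcn-/- libraries (109 to 121).

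The endothelial list was lower in Emcn-/- retinas with camera on values or on ranks (adjusted p = 0.0191 on ranks), and this depended on single libraries and on the scaling. Of 30 tested endothelial members, 23 had negative log2 fold changes, the median was -0.19, and the list was lower than other genes with camera's preset correlation (adjusted p = 0.0367; adjusted p = 0.991 with an estimated correlation). Kdr, the main receptor for vascular endothelial growth factor, went from 3073 ± 79.0 to 2582 ± 288 normalised reads (-0.26 ± 0.08, limma adjusted p = 0.499), and Vwf, a clotting factor of larger vessels, from 621 ± 98.8 to 403 ± 191 (-0.73 ± 0.30, 0.590). No member passed over all genes, and 0 passed when adjusted over the list alone. Pecam1 (0.01 ± 0.20), Cdh5 (-0.25 ± 0.27), Flt1 (-0.09 ± 0.08), Cd34 (0.09 ± 0.19), Mcam (0.31 ± 0.18), Plvap (0.28 ± 0.19), Nrp1 (0.01 ± 0.12) and Dll4 (-0.04 ± 0.33) differed by less than the test could separate. The hypoxia-induced ligand Vegfa was at 2846 ± 415 and 3192 ± 312 (0.17 ± 0.11, limma adjusted p = 0.696). Emcn-/- replicate 2 held the lowest endothelial list mean, -0.63 against 0.03 to 0.26 in the other libraries. Without it the median turned to 0.11 (camera adjusted p = 0.0690), and without Emcn+/+ replicate 3 the call was also lost (-0.15, 0.160), as it was with upper-quartile scaling (-0.20, 0.0586); without Emcn-/- replicate 3 the median was -0.31.

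Other vascular lists did not pass camera at the preset correlation. The list of vascular endothelial growth factor and angiopoietin ligands and receptors had a median of -0.12 (adjusted p = 0.222), pericytes and smooth muscle -0.13 (0.799), basement membrane -0.16 (0.145), Wnt and Norrin signalling with the blood-retina barrier 0.08 (0.0865), Notch signalling -0.03 (0.966) and vascular guidance cues -0.06 (0.183). Leaving out 1 library brought some of them past the threshold: basement membrane without Emcn+/+ replicate 2 (-0.25, 0.000925) or Emcn-/- replicate 3 (-0.32, 0.00111), Wnt and Norrin signalling without Emcn-/- replicate 2 (0.15, 0.000189) and guidance cues without Emcn-/- replicate 1 (-0.19, 0.0429). The pericyte (0.08, 0.0710), Notch (0.08, 0.316) and guidance (0.04, 0.985) medians were positive without Emcn-/- replicate 2, without passing. The growth factor and angiopoietin median ranged from -0.21 to -0.04. Among mural cell genes, the smooth muscle actin gene Acta2 had 106 ± 19.7 normalised reads in Emcn+/+ and 219 ± 35.4 in Emcn-/- (1.04 ± 0.18, limma adjusted p = 0.340), and it was the 1 member higher when adjusted over the list alone. The surface coat list, which holds relatives and partners of endomucin but not Emcn, was at 0.01 (0.799), with 15 members positive and 13 negative of 28, and its median was -0.00 with upper-quartile scaling. Podxl, a sialomucin of the same surface coat, was level at 3884 ± 494 and 3868 ± 271 normalised reads (0.00 ± 0.09, limma adjusted p = 0.999). The retina samples do not show which cells gave the reads of Podxl or Kdr, both far above Pecam1 (458 ± 104 in Emcn+/+).

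**Figure D3:**
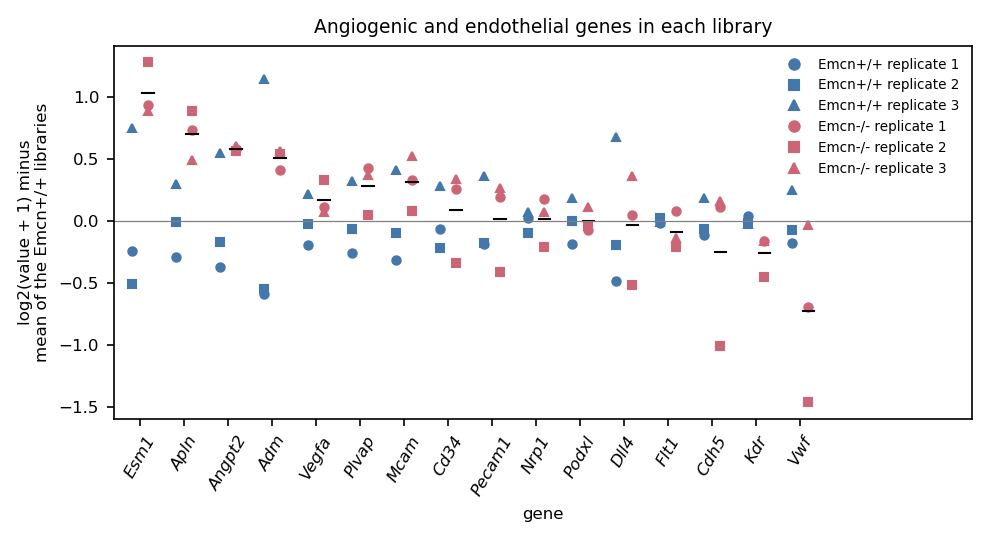
Log2(value + 1) of 16 angiogenic and endothelial genes (horizontal axis) in each library, minus the mean of the Emcn+/+ libraries; each symbol is 1 library and the black line is the Emcn-/- mean. Esm1, Apln and Angpt2 lie above 0 in each Emcn-/- library, and Cdh5 and Vwf are lowest in Emcn-/- replicate 2.

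Hypoxia response genes were higher as a group in Emcn-/- retinas. Of 30 tested members, 23 had positive log2 fold changes, with a median of 0.14 (camera adjusted p = 0.000227; adjusted p = 0.991 with an estimated correlation). The members with the smallest p were the glucose transporter gene Slc2a1 (0.24 ± 0.06, limma adjusted p = 0.400) and the mitophagy receptor gene Bnip3l (0.23 ± 0.07, 0.504). No member passed over all genes or when adjusted over the list alone. The per-library list means were -0.17, -0.19 and 0.18 in Emcn+/+ and -0.01, 0.08 and 0.11 in Emcn-/-, so Emcn+/+ replicate 3 lay above the Emcn-/- libraries (exact permutation p = 0.4 over all libraries, two-sided, n = 3 each). Without that library the list median was 0.25 (camera adjusted p = 1.86e-12).

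Rod and Müller glial lists were also higher with the preset correlation. All 22 rod photoreceptor members had positive log2 fold changes, of small size (median 0.09, camera adjusted p = 0.000847; adjusted p = 0.991 with an estimated correlation), such as the phototransduction genes Gngt1 (0.17 ± 0.07, limma adjusted p = 0.577) and Cnga1 (0.13 ± 0.06, 0.616). None passed over all genes or when adjusted over the list alone, and without Emcn+/+ replicate 1 the list was no longer called (median 0.05, 0.0772). The rod list means of the genotypes overlapped (exact permutation p = 0.3, 2-sided). Of 17 Müller glial members, 12 were positive, with a median of 0.16 (camera adjusted p = 0.0228; adjusted p = 0.991 with an estimated correlation). That call was lost with camera on ranks (adjusted p = 0.0826) and without Emcn-/- replicate 1 (0.0846), and without Emcn+/+ replicate 2 the median was 0.09. The lipid carrier gene Apoe had an estimate of the same size in both fits and passed with DESeq2 (0.37 ± 0.08, adjusted p = 0.000693) but not over all genes with limma (0.37 ± 0.07, 0.374). The same held for the collagen chain gene Col9a1 (0.53 ± 0.11, 0.000764 with DESeq2; 0.54 ± 0.11, 0.374 with limma). The pigment epithelium and ciliary lists were higher by more (medians 0.80 and 0.61), and whether tissue carried over with the retina raised these Müller members was not tested. When adjusted over the list alone, 3 members were higher (Apoe, Col9a1 and the carbonic anhydrase gene Car14) and 1, the transporter gene Abca8a, was lower; over all genes 0 passed. The glial reactivity list did not pass (median -0.08, camera adjusted p = 0.855) but passed downward without Emcn+/+ replicate 1 (-0.34, 0.0390) and upward without Emcn+/+ replicate 3 (0.44, 0.000235), and its marker Gfap was at 1864 ± 1310 and 1803 ± 867 normalised reads (0.07 ± 0.44, limma adjusted p = 0.974).

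Genes of the retinal pigment epithelium, the pigmented layer behind the retina, gave the smallest p among the lists. All 17 tested members had positive log2 fold changes, with a median of 0.80 (camera adjusted p = 2.14e-10; adjusted p = 0.991 with an estimated correlation). The melanin synthesis gene Dct went from 1136 ± 368 to 2436 ± 737 normalised reads (1.11 ± 0.26, limma adjusted p = 0.400) and the transthyretin gene Ttr from 2171 ± 753 to 3950 ± 628 (0.92 ± 0.24, 0.424). When adjusted over the list alone, 8 members were higher (Dct, Lrat, Oca2, Rgr, Rpe65, Ttr, Tyr and Tyrp1), and 0 passed over all genes. The member with the most reads, Otx2, which photoreceptor and bipolar cells also express, had 0.06 ± 0.06. The list means were 0.06, -0.82 and -0.34 in Emcn+/+ and 0.07, 0.49 and 0.55 in Emcn-/- (exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allows). The gap between the genotypes was narrow, and 0.1 was also reached by the cone list, upward, and the horizontal cell list, downward. Ciliary body and iris genes were higher too, with 11 of 12 positive and a median of 0.61 (camera adjusted p = 0.000274, or 0.991 with an estimated correlation). Col9a2 (0.60 ± 0.14, limma adjusted p = 0.400) was the 1 member higher when adjusted over the list alone, Zic1 had 0.61 ± 0.20, and none passed over all genes. Its list means, 0.16, -0.88 and -0.12 in Emcn+/+ and 0.35, -0.06 and 0.56 in Emcn-/-, overlapped (exact permutation p = 0.2, two-sided), and without Emcn+/+ replicate 2 the median was 0.34.

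Interferon response genes were lower in Emcn-/-, with 20 of 21 members negative and a median of -0.76 (camera adjusted p = 0.00160; adjusted p = 0.991 with an estimated correlation). This rested on 1 library: Emcn+/+ replicate 3 had a list mean of 2.17, while the other 5 libraries lay between -0.61 and -0.17, and without it the median turned to 0.14 (camera adjusted p = 0.0746). Without Emcn+/+ replicates 1 or 2 the median was -1.19 and -1.21. The viral RNA sensor gene Ifih1 (-0.92 ± 0.49, limma adjusted p = 0.666) and Ifit2 (-0.55 ± 0.36, 0.708) did not pass, and 0 members passed over all genes or when adjusted over the list alone. The same library was the 1 with reads typical of a female, with 17641 Xist reads and 0 of the Y-linked Ddx3y, against 1 to 5 Xist reads and 1143 to 1393 Ddx3y reads elsewhere. It also had the highest mean of the glial reactivity list, 0.98, and of the microglial list, 0.37. Its value was the highest on the first principal component (38.3, 31.8% of the variance). Emcn-/- replicate 3, of the same title-number series, went the same way (glial reactivity 0.48, microglia 0.16, first component 13.2). The remaining libraries lay below 0 on each of these measures, so apart from the interferon genes this pattern was shared by both libraries of that series.

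**Figure D4:**
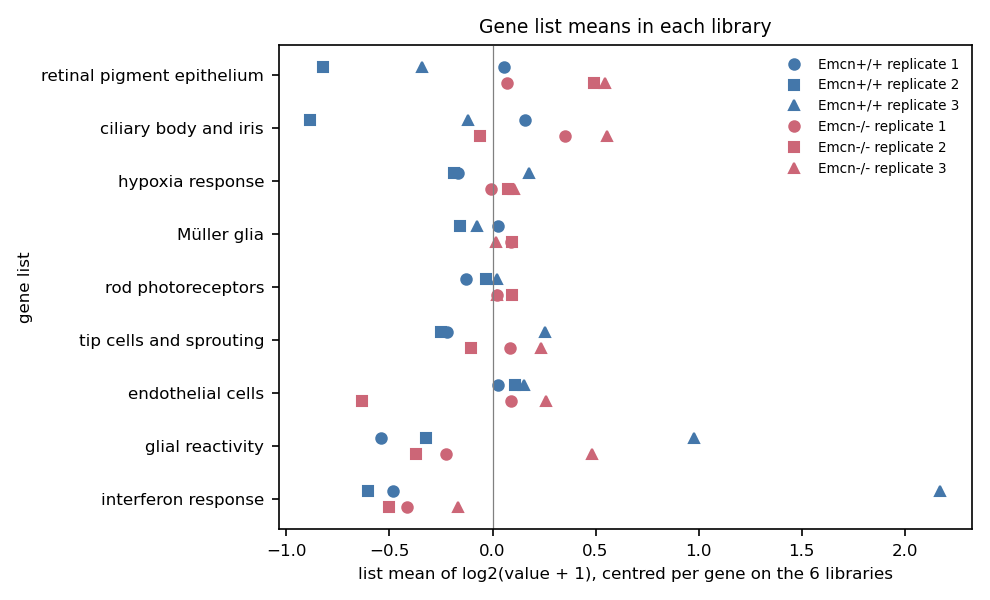
Mean of log2(value + 1) over the tested members of 9 gene lists (vertical axis), centred per gene on the 6 libraries (horizontal axis); each symbol is 1 library. The pigment epithelium list separates the genotypes narrowly, at 0.06 in Emcn+/+ replicate 1 and 0.07 in Emcn-/- replicate 1. Emcn+/+ replicate 3 stands apart at 2.17 for the interferon list and Emcn-/- replicate 2 at -0.63 for the endothelial list.

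Lists of other retinal cells did not pass camera at the preset correlation. The medians were 0.10 for cones, the photoreceptors of colour vision (adjusted p = 0.164), -0.04 for bipolar cells (0.183), 0.03 for amacrine cells (0.836), -0.17 for horizontal cells (0.183), 0.02 for retinal ganglion cells (0.564), 0.07 for astrocytes (0.737) and -0.06 for microglia and macrophages (0.665). The inflammation and leukocyte adhesion list had -0.15 (0.529), the cell cycle list 0.09 (0.814), immediate early genes 0.13 (0.237), vascular endothelial growth factor responsive genes 0.05 (0.764), stress response genes 0.09 (0.183) and BMP and TGF-beta signalling 0.07 (0.183). Without Emcn+/+ replicate 2, microglia (-0.19, 0.0390), inflammation (-0.27, 0.0181) and cones (0.10, 0.0181) passed. Microglia and inflammation turned upward, without passing, when Emcn+/+ replicate 3 was left out (0.15, 0.131 and 0.16, 0.507), and inflammation also without Emcn-/- replicate 2 (0.02, 0.908). Without Emcn+/+ replicate 3, bipolar cells (-0.05, 0.0291), amacrine cells (-0.12, 0.0430), immediate early genes (0.26, 0.000357) and stress response genes (0.17, 0.000844) passed. Without Emcn-/- replicate 2, bipolar cells (-0.08, 0.0447), horizontal cells (-0.24, 0.0325), stress response genes (0.12, 0.0226) and BMP and TGF-beta signalling (0.14, 0.00892) passed, the last also without Emcn+/+ replicate 1 (0.07, 0.0485). Lens crystallin RNA was found mainly in Emcn+/+ replicate 1, where Cryaa stood at 20468 normalised reads against 5.46 to 82.3 in the other libraries (lens list median -1.49, camera adjusted p = 0.164). The lens list passed upward without that library (1.13, 6.02e-06) and downward without Emcn+/+ replicate 2 (-2.76, 0.000192) or replicate 3 (-2.86, 0.00186). Of the remaining tissue lists, mitochondrially encoded genes had -0.02 (0.814) with mt-Co1 at -0.02 ± 0.08, skeletal muscle -0.19 (0.183) with Mylpf at 0.38 ± 0.27, erythroid cells -0.08 (0.984) with Bpgm at 0.02 ± 0.08, the corneal and fibroblast list -0.03 (0.737) with Fbln1 at 1.15 ± 0.51, and the oligodendrocyte list 0.03 (0.437) with Cnp at 0.03 ± 0.16. Leaving out 1 library moved the skeletal muscle median to as low as -0.63 (without Emcn+/+ replicate 3). The erythroid median ranged from -0.53 (without Emcn-/- replicate 3) to 0.11 (without Emcn-/- replicate 1), and neither list passed. With weakly expressed members kept, the corneal median was 0.54 (0.0814) and the oligodendrocyte list passed (0.57, 0.0358). Median and mean differed in sign for the mitochondrial list (mean 0.01), pericytes (0.00), the surface coat list (-0.02) and the corneal list (0.13), and the test's direction was upward for the corneal, erythroid and surface coat lists. The 18S ribosomal RNA gene took 0.185% of the reads in Emcn+/+ replicate 2 and between 4.29% and 6.78% in the other 5 libraries.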

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

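The fits with the length trend removed, the rod list mean as a covariate and list exclusions were chosen after the results were seen. The same holds for limma with TMM scaling, pseudocount 5 and the unfiltered DESeq2. Emcn kept its direction under all alternatives, with log2 fold changes from -5.23 to -3.70. Its call was lost in 3 fits with 1 library left out (range of log2 fold changes -5.23 to -4.50, adjusted p 0.00652 to 0.209) and with the rod covariate (-4.55, adjusted p = 0.399). With 1 library left out the count of higher genes ranged from 0 to 37 and of lower genes from 0 to 110, both highest without Emcn+/+ replicate 3. That library is the only one with female reads, so the sex covariate fits it alone (40 higher, 113 lower), and 1 surrogate variable gave 49 and 143. DESeq2 called 13 higher and 59 lower, or 14 and 35 without its filter, and the rod covariate 0 lower; the cause was not tested. Without Emcn+/+ replicate 3 and with the length trend removed, 8 were higher and 3 lower. Other scalings, filters and pseudocounts, the number-series block and gene type left 1 lower and 0 higher. No paired analysis was possible because the replicate numbers follow only the order of the samples. The number-series block sets replicate 3 of both genotypes apart from the other libraries. With it, the genes with an unadjusted limma p under 0.05 rose from 1358 to 2091. Leaving out Emcn+/+ replicate 3 keeps the series of these replicates in Emcn-/- only, so those fits do not balance series and genotype.

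The count of higher lists was 5 and ranged from 4 to 9 with 1 library left out, and lower lists, 2, from 3 to 6 (highest without Emcn+/+ replicate 2). Higher lists numbered 10 with no low-value filter (tip cells, cones, oligodendrocytes, BMP and Wnt signalling added), 9 with the sex covariate, 9 with 1 surrogate variable, 8 with the rod covariate and 10 without Emcn+/+ replicate 3 and the length trend, where 4 were lower. Leaving out the neighbouring-tissue and interferon lists left 3 higher and 0 lower; 3 of the lists called before were among those left out, and the endothelial list was lost (adjusted p = 0.0518). Upper-quartile scaling left 1 lower, the endothelial list being lost there too. Camera on ranks lost the Müller list. An estimated correlation gave 0 and 0, as did fry's directional test; fry's mixed test called 1, horizontal cells (adjusted p = 0.00643). The pigment epithelium, hypoxia and ciliary lists stayed called with each library left out (highest adjusted p 3.57e-07, 0.0328 and 0.00384).

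Directions turned for several lists, and the cause was not tested. With 1 library left out, medians ranged from -2.86 to 1.13 for lens (upward without Emcn+/+ replicate 1), -0.35 to 0.44 for glial reactivity, -0.12 to 0.0871 for amacrine cells and -1.21 to 0.14 for interferon genes (each turned without Emcn+/+ replicate 3), and -0.31 to 0.11 for endothelial cells. The sex covariate gave 0.44 for glial reactivity, -0.12 for amacrine cells and 0.14 for interferon, and 1 surrogate variable 0.22 for glial reactivity. Without Emcn+/+ replicate 3 and the length trend the values were 0.46, -0.11 and 0.18, with -0.0745 for ganglion cells. The rod covariate gave -0.00493 for endothelial cells, 0.00743 for rods and 2.46 for lens. Depth limits the low genes: at 1 normalised read per read, Emcn in Emcn-/- rests on 1 to 5 reads per library.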

Other observations

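Apart from the counts over splits, the tests weighed below were chosen after the gene and list results were seen. For the tests of length slopes, 18S share, lists with the length trend removed, library overlap and exact permutation, the readings were also written after their values were seen; for the other tests they were written before. Onecut2 and Onecut3, transcription factor genes of horizontal cells, had lower values in Emcn-/- retinas without passing over all genes. Onecut2 was at 142 ± 10.2 normalised reads in Emcn+/+ and 97.3 ± 4.16 in Emcn-/- (SD, n = 3; log2 fold change -0.54 ± 0.13 SE, limma adjusted p = 0.400) and was the 1 horizontal cell member lower when adjusted over the list alone. Onecut3 was at 85.1 ± 8.21 and 61.4 ± 13.0 (-0.48 ± 0.20, limma adjusted p = 0.594). The list of 8 tested members passed fry's mixed test (adjusted p = 0.00643), with 3 members positive and 5 negative, and did not pass camera (adjusted p = 0.183). These genes were chosen after their values were seen, as were those of the next paragraph.

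DESeq2 called Col9a3, a chain of collagen IX like Col9a1 (0.62, adjusted p = 0.0136), and the matrix protease inhibitor gene Timp3 (0.59, adjusted p = 0.00704), both higher. The limma values were 0.63 ± 0.16 for Col9a3 and 0.62 ± 0.16 for Timp3, with adjusted p of 0.424 and 0.400. Without Emcn+/+ replicate 3, limma called the nuclear RNA gene Malat1 lower (-1.03, adjusted p = 0.00973) and the hypoxia-induced gene Ndufa4l2 (0.97, 0.00973), Bnip3 (0.45, 0.0164), the metallothionein gene Mt1 (0.72, 0.0164) and A2m (0.85, 0.0164) higher. In the library left out, 81 of the 110 lower and 30 of the 37 higher genes lay on the Emcn-/- side of the midpoint between the other libraries' genotype means. Apart from Emcn, these genes were called only without that library, so its position is largely built into their choice. The share over all genes was not computed, and no conclusion on the library is drawn from these counts.

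Long genes had lower values in Emcn-/- retinas. The slope of the log2 deviation on log10 exonic length was 0.18, 0.17 and -0.08 in Emcn+/+ and -0.01, -0.12 and -0.15 in Emcn-/-, so 2 libraries lay inside the other genotype's range, which is consistent with a length bias that varies between libraries. Removing the length trend left 3 called of the genes called lower without Emcn+/+ replicate 3 (a share of 0.0275) and moved their median log2 fold change from -0.46 to -0.27, so these calls may follow the trend. Uptake of reads by 18S RNA is argued against as the source, since Emcn+/+ replicates 1 and 2, at 5.02% and 0.185%, differed in slope by 0.0471 of the genotype difference. A genotype effect on long genes cannot be told apart from library variation with 3 against 3 (exact permutation p = 0.2, 2-sided). GC content of the transcripts had a trend as well. Its slope was -0.23, -0.14 and 0.15 in Emcn+/+ and 0.01, 0.21 and 0.01 in Emcn-/-. The length and GC trends were not told apart.

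Pigment epithelium and ciliary genes had higher values in Emcn-/- and passed as lists with the preset correlation (adjusted p = 0.991 for both with an estimated correlation). Within genotypes the pigment epithelium members deviated together (mean pairwise correlation across genes 0.431, against 0.0944 at the 95th percentile of 1000 random lists matched on expression). Different amounts of that tissue carried over in dissection would give this. The random lists were matched on expression only, so any genes that vary together would pass, and the test does not favour carried tissue. Gene length is argued against as the source, because the list still passed with the trend removed (camera adjusted p = 4.21e-11; range over alternatives with the preset correlation 1.49e-16 to 5.18e-07; adjusted p = 0.991 with an estimated correlation). A genotype effect on these genes cannot be told apart from carried tissue, since the exact permutation p of 0.1 is the smallest possible here.

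Hypoxia genes were higher in Emcn-/- as a list with the preset correlation (adjusted p = 0.991 with an estimated correlation), and no member passed over all genes. Gene length is argued against as the whole source (camera adjusted p = 7.73e-05 with the trend removed; range over alternatives with the preset correlation 1.86e-12 to 0.971). In 1 Emcn+/+ library, replicate 3, the list mean lay at or above the lowest Emcn-/- library, which is consistent with variation between libraries that does not follow genotype. A larger share of rod RNA cannot be told apart from it. With the rod list mean as a covariate the call ended (camera adjusted p = 0.971) and the median went from 0.14 to 0.01. The rod means followed genotype in part, so the covariate also takes up some of the genotype difference. They were -0.13, -0.03 and 0.02 in Emcn+/+ and 0.02, 0.10 and 0.02 in Emcn-/- (exact permutation p = 0.3, 2-sided). A genotype effect stays open as well (exact permutation p = 0.4, two-sided).

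The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With limma the real split gave 1 gene and the highest other 3, with 2 of 10 splits giving as many. With DESeq2 the real split gave 72 genes, the highest other 464, and 2 of 10 gave as many. With camera the real split gave 7 lists, the highest other 23, and 10 of 10 gave as many. No split gave fewer lists than the real one, so the number of called lists does not set genotype apart from other groupings. The split with 3 and 464 genes set Emcn+/+ replicates 1 and 2 with Emcn-/- replicate 1 against the rest, which points to a structure among the samples that crosses genotype. The 3 libraries set together had the highest length slopes (0.18, 0.17 and -0.01, against -0.08, -0.12 and -0.15 in the rest). They also had the lowest GC slopes. Whether either trend gave these calls was not tested.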
